A study of Mus musculus with 357 samples.

How the data were processed

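Single HSCs (lineage-negative, positive for Sca1, c-kit and CD150, negative for CD48) were isolated by flow cytometry from bone marrow of Col1a1-tetO-H2B-mCherry mice, 2 or 5 weeks after labelling. Per the labels' protocols, each cell was lysed in its own plate well, its RNA was reverse transcribed, and the cDNA went through 22 cycles of multiplex pre-amplification with 96 gene assays, exonuclease treatment to remove primers and a 5-fold dilution. Quantitative PCR with EvaGreen, a dye that binds double-stranded DNA, then ran for 30 cycles on a microfluidic dynamic array, followed by a melting curve. The authors deposited threshold cycles that were not normalized, 1 per assay and cell, with 999 for a reaction with no product. The Ct is the cycle at which the fluorescence passes a threshold, so a Ct lower by 1 means about 1 doubling more template. The software and thresholds that set the Ct and that marked failed reactions are not given in the sources used here, and EvaGreen reports any double-stranded product, so a late product can be a non-specific one. No wells without a cell were analysed here.

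The labels give each cell its chase time and plate, and all 357 cells were mapped. They name no animal, so the cells of 1 chase time counted as 1 sample and no p value, standard error or test between times was computed. The plates, 2 per chase time, were the only repeated unit, and they may be technical repeats. An assay was called apart when both 5-week plates lay above, or both below, the 2-week plates. Chance alone gives this for 33.3% of assays if no plate shares tie. With 2 plates against 2 the smallest permutation p would be 0.333.

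A product was called detected at Ct 25 or below. Values ranged from 8.56 to 27.6, and 60 products were later than 25. A well was kept if at least 20% of the assays were detected, and no well was removed. No 2 cells had identical values. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. For a share of 0 a limit of 3 counts over the cells examined was also used, or 1.64% of 183 cells, 1.72% of 174 and 0.84% of 357. It is tighter than the exact interval, which reaches 2.00% for 183 cells and 2.10% for 174. Reference assays were those detected in at least 95% of cells on every plate: Actb, Ccnd2, CDK4, Etv6, Gapdh, Gata2, Hlf, Kit, Ldb1, Lmo2, Meis1, Nfe2, Trp53 and Zfpm1. Level was the mean Ct of these 14 assays in a cell minus the Ct of the gene, averaged over detecting cells, for the 80 assays with at least 10 detecting cells on each plate. Several genes reported here (Kit, Nfe2, Zfpm1, Actb, Gapdh) are among the 14, so their own levels enter the centring.

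Gene lists were compared by the median difference in detection share, set against 10000 random lists of the same size drawn in 3 bins of detection share, for lists with at least 4 measured members. Co-variation was Spearman's and Pearson's correlation across the cells of each plate, with undetected reactions at the limit, for assays detected in at least 10% of cells on every plate. The Ct was used as deposited for this, not centred on the reference Ct of the cell. Cells were not clustered, since all had 1 sorted phenotype. Of 15 markers of mature blood cells and 10 of endothelium and stroma fixed as a check on the sort, 0 were among the 96 assays.

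Assay names were matched to the mouse symbols of the RefSeq annotation of GRCm38.p6: 82 matched as printed, 12 in another case and 1 by a synonym, and 1 (Sfpi) was kept as the file names it. Sfpi therefore entered no gene list. No build is named in the sources used here, and no coordinates are given. The computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0.

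The steps were tested on simulated plates of 96 assays with 12 of them changed. A change of 20 points in share was recovered as 19.9 on average, a change of 1 log2 unit in level as 1.04, and 11 of the 12 changed assays had plates apart in the true direction. Of 44 unchanged assays detected in 10 to 90% of cells, 11 (25.0%) had plates apart. In 100 assays that followed only a covariate that differed between times, the adjustment for it lowered the mean difference from 13.8 to 1.1 points.

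The lists, the Ct 25 limit, the well filter, the centring and the rule for named genes were fixed before the data were examined. The rule took, among assays with plates apart, up to 10 with the largest gain and 10 with the largest loss in share (7 had a loss) and 5 of each in level. It added the sort genes, the reference genes, up to 4 members per list by absolute difference in share, the 5 most and 5 least detected assays, and the 10 highest and 5 lowest pairs on their weakest plate. A gene that this rule took is not reported here. Alternatives also fixed then were other Ct limits, other centrings, levels over all cells, other well filters, equal weight of plates, each plate left out in turn, a logistic fit with the number of detected assays as covariate, and pairs restricted to jointly detected cells or with the trend on detected assays removed. Alternatives chosen after the data were seen included a Ct limit of 18, because 8.98% of products lay later than it. Also chosen then were the reference Ct as covariate, leaving out assays of mostly late products, and levels relative to the plate median. The Ct 18 limit cut through the range of some assays, such as ndn with plate means from 17.0 to 18.0. For assays with mostly late products, such as Nkx2.3 and Dntt, it left out most products.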

Results

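Single hematopoietic stem cells (HSCs) from mouse bone marrow were profiled by reverse transcription and quantitative PCR with 96 gene assays. The cells came from mice in which a fluorescent histone, H2B-mCherry, had been induced. The label is diluted when a cell divides, and the cells were isolated 2 or 5 weeks after labelling. All were sorted by the surface phenotype Lin-Sca1+c-kit+CD48-CD150+. The 2-week time held 90 cells on its plate 1 and 93 on its plate 2, and the 5-week time held 91 on its plate 1 and 83 on its plate 2. The table held 34272 reactions, of which 13989 (40.8%) had no product. A cell had a product at threshold cycle (Ct) 25 or below in 54.6 ± 5.36 assays (SD over the cells of both plates) at 2 weeks and in 58.8 ± 5.71 assays at 5 weeks. The mean Ct of the 14 assays detected in nearly every cell was 13.4 ± 0.53 (SD) at 2 weeks and 13 ± 0.65 at 5 weeks, a difference of -0.49 cycles. The labels name no animal, so each chase time counted as 1 sample, no test was made between the times, and intervals are exact Clopper-Pearson 95% intervals that cover counting error only. Each plate held 1 chase time, so plate or chip and chase time could not be told apart.

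The first comparison asked how the genes that HSCs expressed differed between 2 and 5 weeks of chase. Cdkn1b, which encodes the cell cycle inhibitor p27, had the largest gain among assays whose plates did not overlap. It was detected in 50.8% of cells at 2 weeks (interval 43.3 to 58.3%) and in 88.5% at 5 weeks (82.8 to 92.8%). Its plate shares were 46.7 and 54.8% against 89 and 88%. Mdm2, whose product drives the degradation of p53, was detected in 51.9% of cells (44.4 to 59.3%) and 75.3% (68.2 to 81.5%). Prmt2, an arginine methyltransferase, was detected in 17.5% (12.3 to 23.8%) and 40.2% (32.9 to 47.9%) of cells.

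Other assays with large gains covered transcription factors and cell cycle genes. The homeobox gene pbx3 gained 20.7 percentage points, from 22.4 to 43.1% of cells. Cebpb, a transcription factor of granulocytes and monocytes, gained 19.7 points, from 14.2 to 33.9%. Ccnd1, which encodes cyclin D1, gained 19.5 points, from 43.7 to 63.2%, and CDK2, a kinase that acts at entry into S phase, gained 18.9 points, from 54.6 to 73.6%. Cers4, a ceramide synthase, gained 21 points, from 61.2 to 82.2%, and 13.4 points when only products at Ct 18 or below were counted. Fos, an immediate early gene of the AP-1 complex, was detected in 13.1% of cells at 2 weeks and in 40.8% at 5 weeks, with 52.7 and 27.7% on the 5-week plates. The homeobox gene Nkx2-3 (assay Nkx2.3) was detected in 43.7 and 71.3%. Products later than Ct 18 made up 51% of the Fos products and 99% of those of Nkx2-3, and without them the differences were 1.22 and 1.15 points. The mean Ct of Nkx2-3 lay between 19.8 and 21.5 on the plates. Its value at Ct 18 therefore leaves out nearly all its products and cannot bear on its gain. With the mean reference Ct of each cell as a covariate, the gains of Mdm2, pbx3, Ccnd1 and CDK2 were 13.5, 12.7, 9.27 and 7.63 points.

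Ly6a, which encodes Sca1, was the assay with the largest loss among those with plates apart. It was detected in 91.3% of cells at 2 weeks (86.2 to 94.9%) and in 73% at 5 weeks (65.7 to 79.4%), with plate shares of 88.9 and 93.5% against 73.6 and 72.3%. Slamf1, which encodes CD150, was detected in 72.1% (65 to 78.5%) and 55.7% (48 to 63.3%) of cells. Cdkn1a, which encodes the cell cycle inhibitor p21, was detected in 12% (7.69 to 17.6%) and 2.87% (0.94 to 6.58%). The transcriptional repressor Gfi1 was detected in 13.7 and 8.05% of cells, and its difference of -5.62 points was -0.63 with the reference Ct as a covariate. Erg, an ETS family transcription factor, was detected in 100% of cells at 2 weeks and in 96.0% at 5 weeks; without 5-week plate 2 its difference of -4.02 points was -1.10, and its plates overlapped at Ct 18. Csf1r, the receptor for macrophage colony-stimulating factor, was detected in 14.8 and 2.30% of cells, and Dntt, which encodes terminal deoxynucleotidyl transferase, in 8.74 and 6.90%. Late products made up 80.6% of those of Csf1r and 96.9% of those of Dntt, and without them the differences were 0.66 and -0.55 points.

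Across the 96 assays, 41 were detected in more cells at 5 weeks on both plates than on either 2-week plate, and 7 in fewer. The plates overlapped for the other 48. The 50% of assays with plates apart compares with 33.3% for chance alone, and splitting the plates by plate number or crosswise set 20 and 16 assays apart. The 33.3% is an upper value, since 8 assays had equal shares on all plates and could not be apart. All 96 assays were read in the same cells, so they are not independent and a shift of a whole plate moves many together. The median difference over all assays was 2.85 points. Without 2-week plate 1 the counts were 59 and 15, where chance for 1 plate against 2 is 66.7%.

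**Figure D1:**
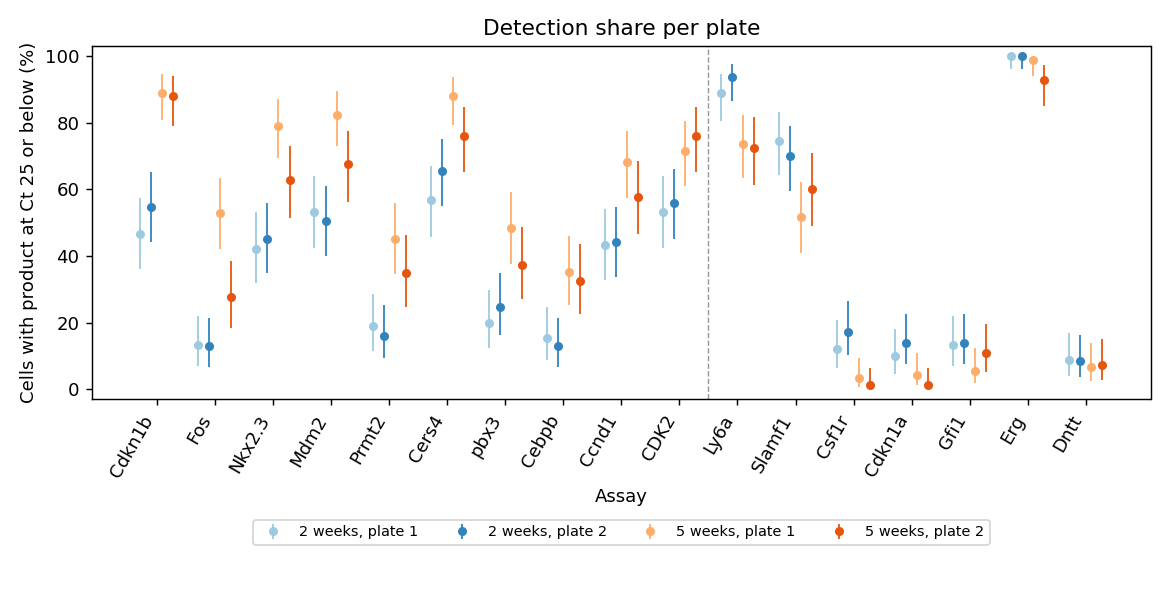
Share of cells (%, vertical axis) with a product at Ct 25 or below on each of the 4 plates, for the 10 assays with the largest gains (left of the dashed line) and the 7 with losses and plates apart (right). Bars are exact 95% intervals for counting error; Cdkn1b lay at 46.7 and 54.8% on the 2-week plates and at 89 and 88% on the 5-week plates.

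The level of a gene in the cells that had its product was measured as the mean reference Ct of the cell minus the Ct of the assay, in log2 units. Nfe2, a transcription factor of megakaryocytes and erythroid cells, was at -2.36 ± 0.82 (SD, n = 90 and 92 cells on the plates) at 2 weeks and -1.42 ± 0.78 (n = 91 and 83) at 5 weeks, a difference of 0.95 with plate comparisons from 0.65 to 1.23. Zfpm1, which encodes the GATA cofactor FOG1, differed by 0.75, with plate comparisons from 0.69 to 0.82. Tcf3, which encodes the E2A proteins, differed by 0.80, and Tgm2, a transglutaminase, by 0.68. Ly6a was at -0.06 ± 1.57 (SD, n = 80 and 87 cells) and -1.61 ± 2.04 (n = 67 and 60), a difference of -1.55 with plate comparisons from -1.70 to -1.38. Ly6a was both detected in fewer cells and lower in the cells that had it.

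For other assays the difference in level was smaller without late products or without 1 plate, or had no value at Ct 18. Flt3, a receptor of lymphoid and multipotent progenitors, differed by -2.36, and by -0.81 with plates still apart among products at Ct 18 or below. Gata1, the erythroid and megakaryocytic transcription factor, differed by -2.32, and by -0.22 with plates overlapping at Ct 18. Fos differed by -3.44 among detecting cells, with plate comparisons from -5.24 to -0.18 and levels of -8.05 and -3.86 on the 5-week plates. Over all cells, with undetected reactions set to the limit, Fos differed by 0.61. Trib2, which encodes a pseudokinase, differed by 1.15, with plate comparisons from 0.23 to 2.30. Of its products 67.1% were later than Ct 18, and Trib2 had no level there. The zinc finger gene Zfp37 differed by -4.25, and by -1.61 without 2-week plate 1.

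Of the 80 assays with a level, 24 were higher and 35 lower at 5 weeks with plates apart, and these counts depended on the centring. They were 49 and 6 without centring and 45 and 9 with centring on Actb and Gapdh. The median level difference over assays was -0.13 with the 14 reference assays, 0.37 without centring and 0.25 with Actb and Gapdh. Relative to the plate median, 34 assays were higher and 14 lower, and on that scale Nfe2 differed by 1.16, Tcf3 by 1.03, Zfpm1 by 0.98, Tgm2 by 0.90 and Ly6a by -1.32. Without centring the same 5 differences were 1.44, 1.27, 1.25, 1.18 and -1.02, and over all cells that of Ly6a was -3.33. The split relative to the plate median turned with other settings, to 24 higher and 25 lower at Ct 23, 21 and 27 of 70 assays at Ct 18, and 15 and 42 over all cells.

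The genes behind the sorting phenotype (Kit, Ly6a, Slamf1 and Cd48) were examined in 1 list with Cd34 and Flt3, which are not part of the stated phenotype. Kit, which encodes the stem cell factor receptor c-kit, was detected in 98.9 and 99.4% of cells at 2 and 5 weeks, and its level differed by 0.15 (0.37 relative to the plate median, 0.65 without centring and 0.53 with centring on Actb and Gapdh). Cd48 was detected in 2 cells at 2 weeks and 3 at 5 weeks, 1.09% (0.13 to 3.89%) and 1.72% (0.36 to 4.96%), all with late products. Cd34, a sialomucin that is low or absent on the surface of many adult mouse HSCs, was detected in 60.7% (53.2 to 67.8%) and 77% (70 to 83%), with plate shares of 61.1 and 60.2% against 78 and 75.9%. Its level differed by -0.17 with plates overlapping, and by 0.31 without centring. Flt3 was detected in 47 and 47.1% of cells, and its difference was -15.4 points at Ct 18. Slamf1 differed in level by -0.57, and by -0.13 without centring. Of the 6 measured members 1 was higher, 2 were lower and 3 overlapped, and their median difference of 0.33 points lay at percentile 11.9 of 10000 random lists matched on detection share. At Ct 18 the median was -7.72 points, at percentile 0.435, and without 5-week plate 1 it was -3.07.

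**Figure D2:**
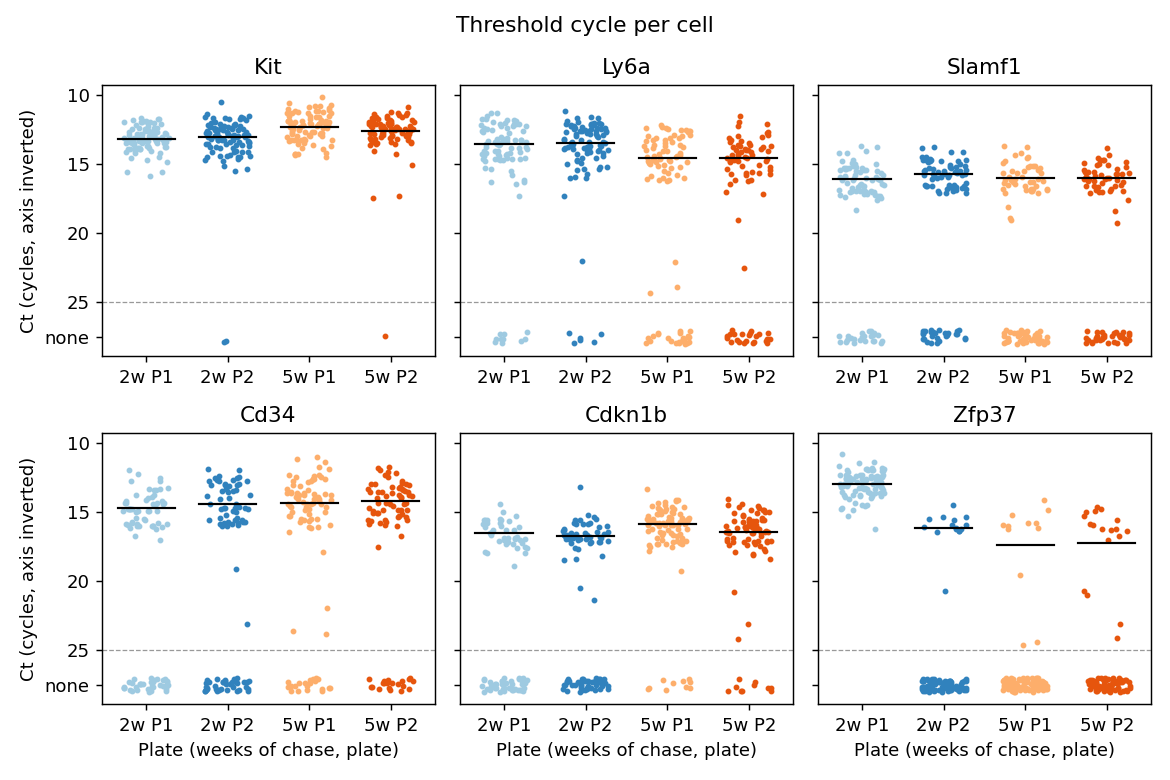
Ct in single cells (vertical axis, cycles, inverted so that more template lies higher) on the 4 plates (2w and 5w, weeks of chase; P1 and P2, plate) for 6 assays. Each point is a cell, points at none had no product, black lines are means over detecting cells and the dashed line marks Ct 25; Ly6a was detected in 91.3% of cells at 2 weeks and 73% at 5 weeks, and Zfp37 in every cell of 2-week plate 1.

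Genes of the megakaryocyte and erythroid list were detected in more cells at 5 weeks, with plates apart for 7 of its 8 measured members. Vwf (assay vwf), which encodes von Willebrand factor, was detected in 34.4% of cells (27.6 to 41.8%) and 51.1% (43.5 to 58.8%), with plate shares of 34.4 and 34.4% against 50.5 and 51.8%. Itga2b, which encodes CD41, gained 11.3 points, with plate comparisons from 4.58 to 17.4. Gata1 gained 8.64 points, with plate comparisons from 7.56 to 9.73. Epor, the erythropoietin receptor, gained 8.57 points, with plate comparisons from 0.57 to 16.3. The list's median difference was 6.14 points, at percentile 88.2 of the random lists, and 3.48 points at percentile 76.4 at Ct 18. With the reference Ct as a covariate the list's median was -0.90, Itga2b -7.28, Epor -6.65 and Gata1 -0.90 points. Nfe2, detected in nearly every cell, had no value in that fit, so this median is not over the same members as the 6.14. The vwf difference of 16.7 points was 9.49 with that covariate and 6.55 with the number of detected assays. Late products made up 86.4% of those of Itga2b, and at Ct 18 the difference of Gata1 was 1.74 points with plates overlapping.

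Cell cycle genes and their inhibitors did not move as blocks. Of 9 measured cell cycle genes 3 were higher with plates apart, namely CDK2, Ccnd1 and Ccnd3, the last a D-type cyclin detected in 90.2 and 98.3% of cells. None was lower with plates apart and 6 overlapped, among them the replication licensing factor Cdt1 with a difference of -5.99 points, which was 0.16 at Ct 18 and -20.5 with the reference Ct as covariate. Late products made up 70.3% of those of Cdt1, so its value at Ct 18 leaves out most of them and cannot bear on its difference. The list's median was 0.0 points (percentile 5.87), and its members CDK4 and Ccnd2 were detected in every cell at both times. Without 2-week plate 2 the median was 4.94 points. Of 13 inhibitors and quiescence genes 3 were higher, 2 lower and 8 overlapped. Cdkn1b gained 37.7 points and Cdkn1c, which encodes the inhibitor p57, gained 7.77, while Cdkn1a and Gfi1 were lower. Ndn (assay ndn), which encodes the growth suppressor necdin, differed by 5.98 points with plates overlapping, and by 13.5 with plates apart at Ct 18. At Ct 18 the difference of Cdkn1c was 1.74 points with plates overlapping. The list's median was 2.97 points (percentile 36.6), 0.77 without 2-week plate 2 and -0.91 with the reference Ct as a covariate. Trp53, detected in every cell, had no value in that fit and was left out of the last median.

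Of 27 measured HSC-associated genes 9 were higher, 4 lower and 14 overlapped, and the median was 1.09 points (percentile 21.9), and -0.57 without 2-week plate 2. Tek (assay TEK), the receptor for angiopoietins, gained 17.9 points, from 47% (39.6 to 54.5%) to 64.9% (57.4 to 72%), and Ly6a was among the lower. Prdm16, singled out after its values were seen, was 1 of the 9, with 0 detecting cells at 2 weeks and 17 at 5 weeks, all at a Ct between 9.17 and 9.86. Zfp37 was detected in 100% of cells on 2-week plate 1 and in 16.1, 13.2 and 21.7% on the other 3 plates, so its difference of -40.1 points rested on 1 plate and was 1.11 without it.

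Of 5 granulocyte and monocyte genes 1 (Cebpb) was higher, 1 (Csf1r) was lower and 3 overlapped, with a median of 1.95 points (percentile 35.7), and -1.46 without 2-week plate 2. Cebpa, a transcription factor needed for granulocytes, was detected in 83.3 and 58.1% of cells on the 2-week plates and in 63.7 and 55.4% on the 5-week plates. Csf2rb, the shared receptor chain for several cytokines, differed by 5.50 points with plates overlapping. The assay Sfpi may stand for Spi1, a gene fixed for this list. Its name matched no symbol, so it was not counted here. It was detected in 74.9% of cells at 2 weeks and 87.4% at 5 weeks, with plates apart. Of 7 lymphoid genes 2 were higher, Tcf3 (4.37 points) and Ikzf1, which encodes Ikaros (4.03 points). Dntt was lower and 4 overlapped, among them Notch1 (4.87 points), and the list's median was 0.13 points (percentile 17.5), and 4.37 without 5-week plate 2. The difference of Ikzf1 was 0.80 points with the reference Ct as covariate, its plates overlapped at Ct 18, and that of Notch1 was 0.54 with the number of detected assays as covariate.

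The remaining lists held few measured members. Ezh1, a histone methyltransferase of the Polycomb group, gained 10.4 points with plates apart, and Cbx7, another Polycomb gene, differed by 6.50 points with plates overlapping. With the number of detected assays as covariate they differed by 6.22 and 1.96 points. Of 3 receptors measured, Tek was higher with plates apart and 2 overlapped. Trp53, Lmo2, Gapdh and Actb were detected in every cell. At the other end, the B lineage factor Ebf1 and the transcription factor Tcf15 were detected in 0 cells on the 4 plates. The limit of 3 counts allows a share of up to 0.84%. Tcf7, a T lineage factor, was detected in 2 cells at each time, and the inhibitor Cdkn2a in 10 cells at 2 weeks and 3 at 5 weeks.

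The second question was which genes varied together between single HSCs. Flt3 and vwf were the pair with the most negative correlation on its weakest plate, with Spearman's rho between -0.34 and -0.27 on the 4 plates (Pearson's r between -0.35 and -0.28). Hlf, a transcription factor of HSCs, was negatively correlated with Itga2b (rho -0.39 to -0.26, r -0.41 to -0.21) and with Gata1 (rho -0.40 to -0.22, r -0.45 to -0.11). CDK6, a kinase of the G1 phase, was negatively correlated with Ly6a (rho -0.40 to -0.25, r -0.31 to -0.18), and Cd34 with Mllt3 (rho -0.58 to -0.22, r -0.46 to -0.13). Among cells in which both products were detected, the CDK6 and Ly6a pair reached 0.07 on its weakest plate and the Gata1 and Hlf pair 0.19.

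Most of the 10 most positive pairs joined broadly detected genes, with Itga2b, found in 45.4% of cells, as an exception. Actb and Gapdh had rho between 0.66 and 0.81 (r 0.65 to 0.80), Actb and CDK4 between 0.65 and 0.75 (r 0.51 to 0.74), and CDK4 and Gapdh between 0.65 and 0.78 (r 0.51 to 0.75). Trp53 followed Gapdh (0.61 to 0.68), CDK4 (0.59 to 0.69) and Actb (0.58 to 0.72). Actb was also correlated with Tcf3 (0.48 to 0.56), Ccnd3 (0.46 to 0.60), Itga2b (0.45 to 0.51) and Zfpm1 (0.44 to 0.50). With products at Ct 18 or below, Actb and Itga2b fell to 0.17 on the weakest plate, and Hlf and Itga2b to -0.08. Once the trend on the number of detected assays was removed, Gata2 and Zfpm1 entered the 10 highest pairs (0.36 to 0.51), and Cd34 and vwf the 5 lowest (-0.52 to -0.29). Among cells with both products the Cd34 and vwf pair ranged from -0.63 to 0.26, with as few as 11 cells on a plate.

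Of 3240 pairs among 81 assays, 1312 (40.5%) were positive and 197 (6.08%) negative on all 4 plates, where chance gives 6.25% for each sign. After removal of the trend the counts were 774 (23.9%) and 436 (13.5%). Neither set of counts was adjusted for the reference Ct of the cell, so a shared amount of cDNA can enter both. These are correlations across 83 to 93 cells of 1 plate, which are not independent replicates, so no p value is given.

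**Figure D3:**
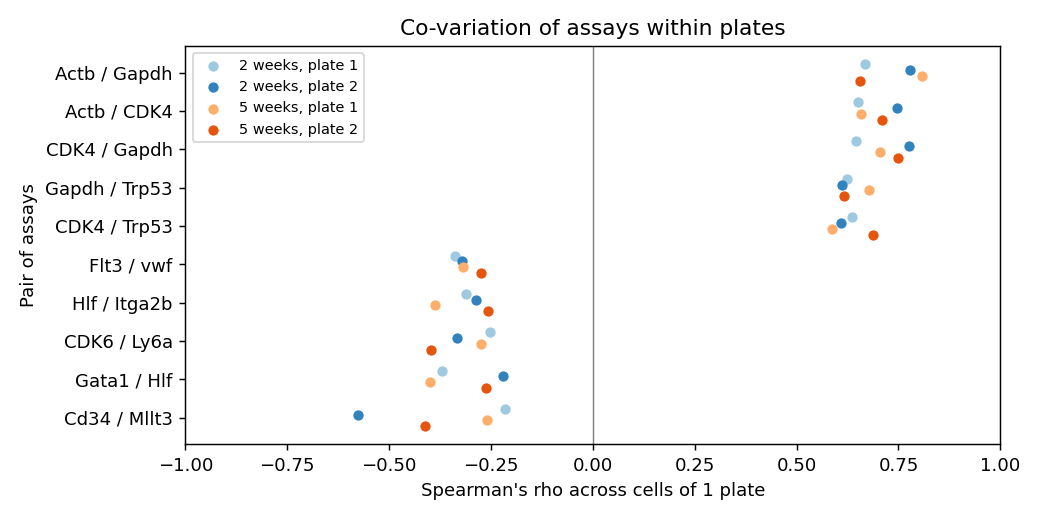
Spearman's rho across the cells of 1 plate (horizontal axis) for 5 of the 10 most positive and the 5 most negative pairs of assays, with 1 point per plate. Actb and Gapdh lay between 0.66 and 0.81 and Cd34 and Mllt3 between -0.58 and -0.22.

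The labels state that expression was related to the division history of each cell. No H2B-mCherry value per cell was analysed here, so that relation was not computed.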

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

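The Ct 18 limit, the adjustment for reference Ct, the omission of assays with mostly late products and the levels relative to the plate median were chosen after the data were seen; the other alternatives were planned. Of the values that sum up a comparison, 59 stayed within their spread or within 1.5 times the count, and 11 moved. Of the values for single genes, lists and pairs, 955 stayed, 66 moved and 11 changed sign. Omitting the well filter changes nothing here, because the filter removed no cell, yet its 73 and 5 values count among those that stayed. The Ct limits of 28 and 30 could change only the 60 products later than Ct 25, and the 40% well filter removed 1 well. All values under these settings also stayed, so the totals overstate how far the results were put to the test. No paired analysis was possible because the comparison rests on no test, and plate and well numbers that recur at both chase times name different plates and cells.

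The count of assays detected in more cells (41) stayed within 1.5 times under Ct limits from 18 to 30 and all well filters. Leaving out 1 plate gave 45 to 59, and for assays detected in fewer cells 13 to 17 in place of 7, since 1 plate against 2 is apart by chance for 66.7% of assays. The counts of levels, 24 higher and 35 lower, were 49 and 6 without centring, because the mean Ct of the 14 reference assays itself differed by -0.49. They were 45 and 9 with centring on Actb and Gapdh, whose own levels against the 14 differed by -0.22 and -0.55. The lower levels numbered 15 over all cells, 21 at Ct 18 and 14 relative to the plate median. Over all cells Fos changed sign to 0.61, because more cells had a Fos product at 5 weeks. At Ct 18 Csf1r changed to 0.66 points, since its loss was of late products.

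With the number of detected assays as covariate, the inhibitors list changed to -1.39 and Epor to -1.48 points. With the reference Ct as covariate, the inhibitors list changed to -0.91, the megakaryocyte and erythroid list to -0.90, Gata1 to -0.90, Itga2b to -7.28 and Epor to -6.65 points. Trp53 and Nfe2 had no adjusted value, so the adjusted medians of their lists are over the other members. Among cells with both products, CDK6 and Ly6a reached 0.07 and Gata1 and Hlf 0.19 on the weakest plate; the cause of the sign changes in this paragraph was not tested. Flt3 and vwf gave no value there, with as few as 6 such cells on a plate. The planned relation to division history was not run. With about 90 cells per plate, rare products such as Cd48 cannot be compared, and 2 plates per time limit every difference.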

Other observations

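The tests of Zfp37 and Prdm16 in this part were chosen after the result was seen. The adjustment for reference Ct was also chosen after the data were seen, though the values for and against were set before it was computed. For the test of the Ly6a axis, the values first set had the wrong sign and were restated after its result was seen. The following assays were singled out after their values were seen. Mettl7a1 (assay mettl7a1), which encodes a methyltransferase-like protein, was detected in 70.5% of cells at 2 weeks and 89.1% at 5 weeks, with plates apart. Tal1, a transcription factor required for blood formation, was detected in 82 and 97.7%, with plates apart. Gfi1b, a transcriptional repressor that acts in megakaryocytes and erythroid cells, was detected in 60.1 and 74.7%, also with plates apart. With the reference Ct as covariate the gain of Mettl7a1 was 22.1 points, that of Tal1 12 and that of Gfi1b 3.16. Ikzf2 (assay IKZF2), which encodes Helios, was detected in 44.3 and 58.6% of cells. Jun, a partner of Fos in AP-1, was detected in 65.6 and 72% of cells on the 2-week plates and 47.3 and 66.3% on the 5-week plates, which overlap.

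Most assays were detected in more cells at 5 weeks, and cells there also had an earlier reference Ct. More amplifiable cDNA per cell may account for part of this. Adjusted for the reference Ct, the median difference over 81 assays was 2.34 points against 4.61 unadjusted, between the bounds set for and against this explanation. For the 10 assays with the largest gain the adjusted median was 18.1 points against 21.9, with single values from 7.63 to 32.9. Since these 10 were chosen by their gain, this decides nothing, and cDNA amount stays open. A difference between chips or runs and an effect of chase time cannot be told apart, because each plate held 1 chase time.

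Zfp37 was detected in every cell of 2-week plate 1, with a mean Ct of 13 there and 16.2 on the other 2-week plate. The chase time does not account for this, since Zfp37 was detected in 16.1% of cells on that other plate. Extra template or product in the wells of plate 1 is a candidate explanation: its Ct was correlated with the cell's reference Ct at rho -0.09, where 23 other assays found in at least 95% of its cells had a median of 0.40 and a percentile 10 of 0.11. Another mix of cells stays open, as 3 assays, Zfp37 and Cebpa among them, differed by over 25 points between the 2-week plates, against 1 between the 5-week plates. No value here separates a real rise of Zfp37 that does not scale with the reference genes.

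Prdm16, a transcription factor of HSCs, was 1 of the assays counted as higher at 5 weeks. It was detected in 0 cells at 2 weeks, for which the exact interval allows up to 2.00%, and in 10 of 91 and 7 of 83 cells at 5 weeks. Its Ct lay between 9.17 and 9.86, earlier than the mean of Actb (11). The SD of its Ct was 0.21, below the lowest (0.59) and the median (1.65) of 16 other assays detected in few cells. This is consistent with a product that does not scale with the cell, such as carry-over. The 5-week plate with fewer of these cells held 41.2% of them, which argues against a fault of 1 plate. A real difference in Prdm16 between the times was not tested in another way.

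A hypothesis was that the loss of Ly6a belongs to a shift along an axis that already separates cells of 1 plate. Since Ly6a was lower at 5 weeks, assays correlated with it within plates would then tend to be lower too, which gives a negative correlation across assays. Across 80 assays, which are not independent replicates, Spearman's correlation between the difference in share and the mean within-plate correlation with Ly6a was 0.06. This decides nothing, because 6 of the 80 were detected in every cell and others in nearly every cell, so that their shares had little or no room to move, and no spread of the value was computed. The hypothesis stays open.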
